A study of Mus musculus with 6 samples.

How the data were processed

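Mouse skeletal stem cells were sorted by fluorescence-activated cell sorting from digested Achilles tendon-to-bone interfaces of C57BL/6 mice, 7 days after a partial injury, and their RNA was sequenced. The enthesis is the graded tissue, partly fibrocartilage, that anchors a tendon in bone. Per the labels' protocols, cDNA was made from 150 pg of total RNA with a SMARTer low-input kit and amplified, and libraries were then prepared by a standard Illumina protocol. At so small an input a transcript present in few copies can drop out of a library or be amplified to a high count, and reads carry no molecular identifiers, so counts are not independent molecules. The surface markers used in the sort are not given in the sources used here.

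The 6 libraries were grouped by the titles and treatment labels into sham control (n = 2), uninjured (n = 1) and injured (n = 3). The description field of the library labelled uninjured names it a sham, whereas its title and treatment label name it uninjured, so it was kept as a group of its own in the main comparison and joined to the sham libraries in a further comparison. The labels do not say whether the libraries come from separate animals or from pools, and p-values therefore measure only the spread between these samples, which may be partly technical.

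The deposited table holds whole-number counts for each gene symbol in each library, and the column totals differ. The values were taken as counts with no scaling between libraries. Unequal totals alone do not exclude scaling by size factors followed by rounding. Per the submitters' processing notes, Salmon 0.12.0, DESeq2 1.22.2 and DESeq were used, and the genome builds GRCm38.p6 and mm9 are both named without a role. How transcript estimates were summed to genes and rounded, and which annotation was used, is not given in the sources used here, and because the build is open no coordinates are given. Whether the counting used strand is not given in the sources used here, so overlapping antisense genes cannot be told apart with certainty. Near-identical copies, such as the osteocalcin genes Bglap, Bglap2 and Bglap3, cannot be told apart with certainty either, because of their shared sequence. Of 26130 genes in the table, 6714 had a count of 0 in all 6 libraries. A spreadsheet had turned 26 gene names into dates, 2 of them occurring more than once; these genes stayed in the tests and are not named. All 6 columns of counts were used.

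Libraries were scaled with the trimmed mean of M-values (TMM) and are given as CPM, counts divided by the scaled library size and put on a common total. Genes were kept by edgeR's filterByExpr with its minimum count of 10. Differences were tested with edgeR 4.0.16 under R 4.3.3, by the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. In the comparison of injured with sham control the fit held all 6 libraries as 3 groups, which left 3 residual degrees of freedom. In the comparison of injured with all non-injured libraries it held 3 libraries on each side and left 4. Standard errors of log2 fold changes were derived from the F statistic. For a gene with no count in a whole group the fitted fold is not used, and a lower bound is given against a floor of 3 counts over that group, which covers counting error only. Levels of gene lists are means over members of log2(CPM + 1), compared by a 2-sided exact permutation test, which cannot go below p = 0.1 for 3 libraries against 3.

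The choice of groups, tests, alternatives, named genes and 27 gene lists was made before the data were examined. The lists cover signalling (TGF-beta, BMP, Wnt, Hedgehog), lineage (tendon and enthesis, cartilage, bone, skeletal stem and progenitor), matrix (collagens and crosslinking, proteases and inhibitors) and processes (cell cycle, inflammatory cytokines, interferon response, hypoxia and glycolysis, oxidative phosphorylation). They also cover immediate early and dissociation stress genes and markers of macrophages, neutrophils, lymphocytes, endothelium, smooth muscle and pericytes, skeletal muscle, erythroid cells, Schwann cells, adipocytes, osteoclasts and epithelium. Of 620 list entries, 2 haemoglobin symbols had no match in the table. Each list was tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 27 lists. The same test with the correlation estimated from these libraries, and fry, were run as alternatives. The genes named are, where no gene passed, the 5 higher and 5 lower with the smallest p in each comparison, up to 4 members of each list with the smallest p against sham control, and a fixed set of stem cell surface markers, TGF-beta genes, Scx, Sox9, Runx2 and Mki67. Any other gene named was chosen after its values were seen. The result of 1 gene is not reported here. The planned position of the uninjured library over called genes could not be given because no gene passed.

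Alternatives were DESeq2 1.42.0, limma-voom, size factors by relative log expression, library size alone, no low-count filter, a filter of 50 counts in 3 libraries, a threshold of 0.1, leaving out each library in turn, sham and injured libraries alone, and a replicate block. The tests were checked on counts simulated from the means of these libraries with 200 changed genes. The changed genes were drawn from the better expressed part of the genes tested, so recovery among the lowest genes is not shown. With the dispersions of these libraries, edgeR recovered 0% of 50 genes changed by 1 log2 unit, 6% at 2 units, 60% at 4 and 88% at 6 in the layout of injured against sham control, where 16752 genes were tested. In the layout of injured against all non-injured, with 14110 genes, the shares were 0%, 2%, 58% and 94%. With a dispersion of 0.05, 48% and 58% were recovered at 1 unit in the respective layouts, and 100% at 2 units and above. With the dispersions of these libraries edgeR also called 17 of 16552 unchanged genes in the first layout and 6 of 13910 in the second, in each a larger share of its calls than the threshold of 0.05. A simulated rise of the cell cycle list was called in each layout, and in the second camera called 2 lists where 1 had been raised. Genes were simulated as independent of each other, whereas the estimated correlation of the cell cycle list was 0.136 and 0.310 in the respective comparisons. The simulation therefore cannot show how camera behaves where list members are correlated.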

Results

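RNA from sorted mouse skeletal stem cells, self-renewing progenitors of cartilage, bone and stroma, was profiled at the Achilles tendon-to-bone interface 7 days after partial injury. The libraries comprised 2 sham controls, 1 uninjured control and 3 injured samples. Total counts were 38382144 and 40483028 in the sham libraries, 37506188 in the uninjured library, and 49952680, 51089267 and 46250870 in injured libraries 1, 2 and 3. Between 14183 (sham 2) and 17281 (injured 3) genes had at least 1 count. Ribosomal RNA genes took 15.0% of counts in sham 1 and 14.7% in injured 1, against 2.89% to 5.32% in the remaining libraries.

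Markers of blood and vessel cells varied widely within groups. Erythroid genes, mainly haemoglobins, took 4.82% of counts in sham 1 and 0.000316% in sham 2, 0.0156% in the uninjured library, and 0.713%, 0.0909% and 0.00101% in injured 1, 2 and 3. Neutrophil genes took 0.987% of counts in sham 1 and 0.585% in injured 1, and at most 0.0912% elsewhere. Macrophage genes took 0.477% in sham 1, 0.630% in injured 1 and 0.229% in injured 2, and at most 0.0272% elsewhere. Endothelial genes took 0.364% in sham 1 and 0.146% in the uninjured library, against 0.00342% in sham 2 and 0.0145% to 0.0619% in the injured libraries. Lymphocyte genes stayed at or below 0.0148% in every library. The largest correlation between libraries was that of injured 2 with injured 3 (Spearman's rho 0.922 across genes, which are not independent replicates). The sham libraries correlated with each other at 0.773, less than sham 2 did with injured 3 (0.914) or with the uninjured library (0.871).

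**Figure D1:**
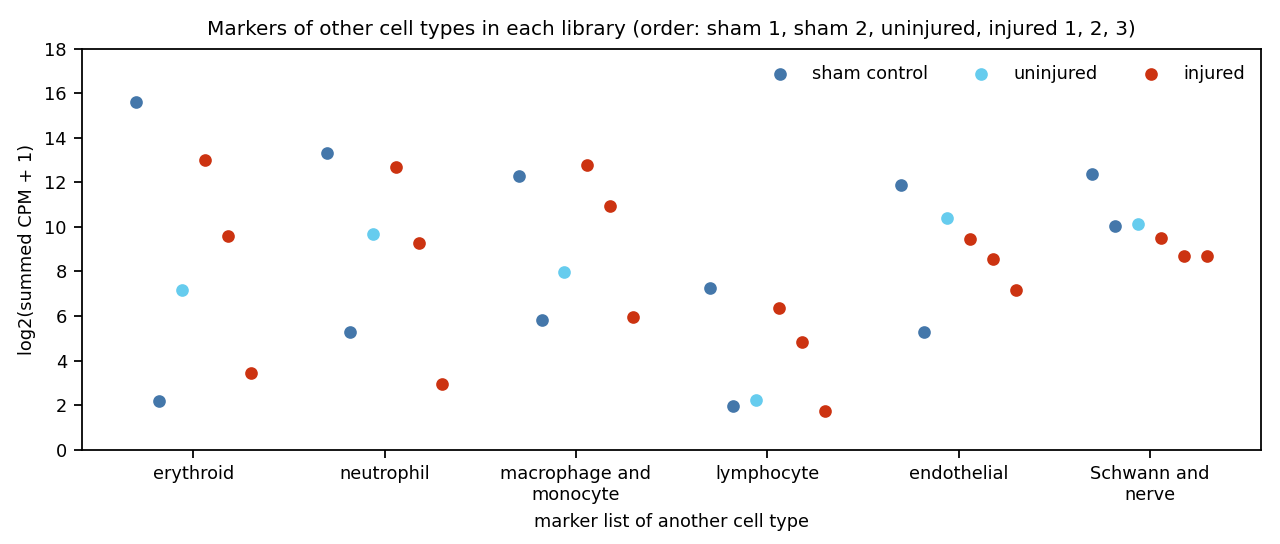
Level of marker lists of 6 other cell types in each library, as log2 of summed CPM plus 1 (y axis), with points in the order sham 1, sham 2, uninjured, injured 1, 2 and 3 within each list and coloured by group. Erythroid, neutrophil and macrophage markers were high in sham 1 and injured 1, and low in sham 2 and injured 3.

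The first comparison asked how stem cells of the injured interface differ from those of sham-operated ones. Cell cycle genes rose together in injured cells: their mean level was 5.06 ± 0.10 log2(CPM + 1) (SD, n = 3) against 3.29 ± 0.73 (SD, n = 2) in sham control, and 30 of 33 members had a fold above 0 (adjusted p = 0.524 with an estimated correlation). Genes of the immediate early response, transcription factors and feedback regulators induced within minutes by growth factors or stress, fell together, from 8.62 ± 0.52 (SD, n = 2) to 7.92 ± 0.24 (SD, n = 3), with 24 of 29 below 0 (adjusted p = 0.899 with an estimated correlation). No single gene passed edgeR's threshold, while DESeq2 called 369. Indian hedgehog (Ihh), secreted by prehypertrophic chondrocytes, stood at 59.0 ± 32.3 CPM (SD, n = 3) in injured cells and had no count in either sham library. Angiopoietin-like 7 (Angptl7) stood at 16.5 ± 3.82 CPM (SD, n = 3) against 1055 ± 396 (SD, n = 2).

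No gene of 16752 tested passed an adjusted p of 0.05 by edgeR's quasi-likelihood test (smallest 0.103), and 778 had an unadjusted p under 0.05, 409 higher and 369 lower in injured. DESeq2 called 369 genes (240 higher, 129 lower), limma-voom 1 (Angptl7, lower) and edgeR without a low-count filter 3 (Ihh higher, C7 and Angptl7 lower). For 87 of DESeq2's genes the sham and injured libraries overlapped, and some of these had counts in 1 library alone. Its split into higher and lower rests in part on such genes. Scaling by library size alone moved the median log2 fold change of all genes from 0.09 to 0.23 and the unadjusted split to 538 higher and 287 lower. Size factors by relative log expression moved them the other way, to 0.02 and to 369 higher and 421 lower. The injured libraries lay wholly above both sham libraries for 1991 genes and wholly below for 1528, together 21.0% of those tested, where chance gives 20%.

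The 10 genes with the smallest p all failed edgeR's adjustment, while each passed DESeq2's at adjusted p between 5.95e-37 and 2.24e-08. Of the 5 that were higher, Ihh was at least 1439-fold above sham control. The neutrophil-attracting chemokine Cxcl5 stood at 174 ± 24.5 CPM (SD, n = 3) against 10.1 ± 4.39 (SD, n = 2), a log2 fold change of 4.11 ± 0.50 (SE). Chondromodulin (Cnmd), an antiangiogenic protein of cartilage, stood at 421 ± 369 against 1.72 ± 0.45 CPM (SD; n = 3 and 2). The cytokinesis motor Kif23, at 28.5 ± 22.2 CPM (SD, n = 3), had no count in sham control and was at least 696-fold above it, and the mitotic gene Gtse1, at 13.2 ± 0.704 CPM (SD, n = 3), at least 323-fold. Of the 5 that were lower, complement component C7 stood at 5.75 ± 1.62 CPM against 220 ± 58.1 (SD; n = 3 and 2), with a log2 fold change of -5.26 ± 0.46 (SE; edgeR adjusted p = 0.103). Angptl7 had the same adjusted p and was 63.9-fold lower on the ratio of the group means. Apolipoprotein D (Apod) differed by -3.25 ± 0.40, tenascin X (Tnxb) by -3.25 ± 0.47, and cartilage intermediate layer protein (Cilp) by -3.30 ± 0.50 log2 units (SE).

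**Figure D2:**
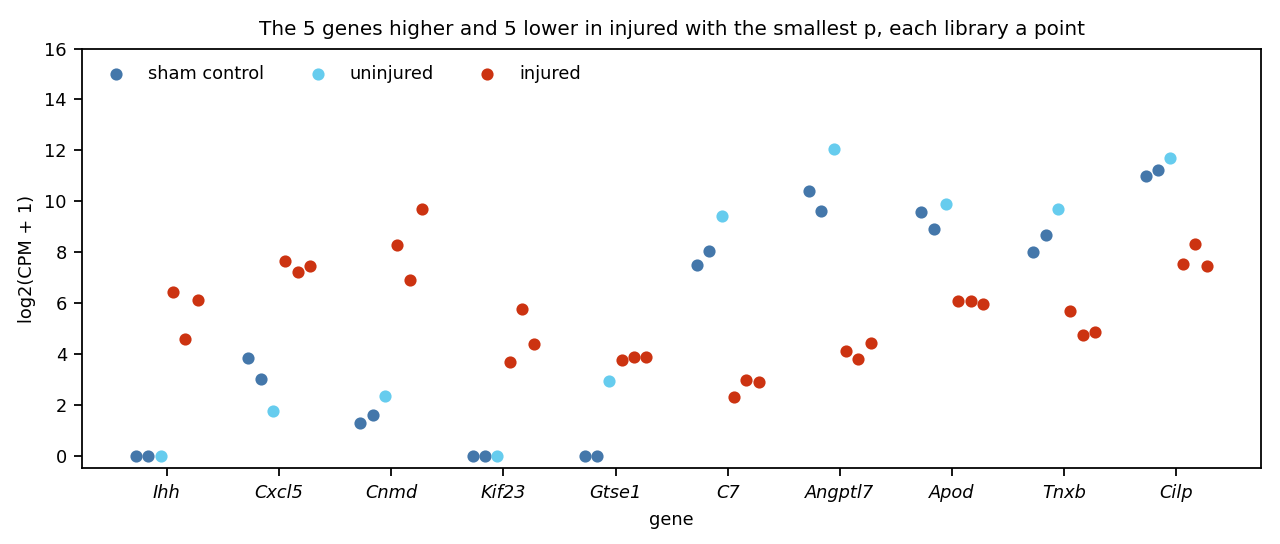
Level of the 10 genes with the smallest p against sham control, as log2(CPM + 1) on the y axis, with 1 point per library in the order sham 1, sham 2, uninjured, injured 1, 2 and 3, coloured by group. For all 10 the 3 injured libraries lie on one side of the sham and uninjured libraries.

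The cell cycle list passed camera at adjusted p = 3.82e-12 and not with the correlation between its genes estimated from these libraries (adjusted p = 0.524 with an estimated correlation). Its median log2 fold change was 1.86, 14 of 33 members had an unadjusted p under 0.05, and 0 passed over all genes by edgeR (6 by DESeq2, all higher), against 1 adjusted over the list alone (Kif23). For 23 members all injured libraries exceeded both sham libraries. Cyclin A2 (Ccna2) stood at 55.4 ± 11.8 against 3.88 ± 3.96 CPM, survivin (Birc5) at 50.6 ± 17.0 against 9.53 ± 3.39, Cenpf at 10.5 ± 5.11 against 0.313 ± 0.130 and Mki67 at 63.6 ± 26.4 against 20.1 ± 17.9 (SD; n = 3 and 2). Injured 3 and sham 2, both poor in blood transcripts, had list levels of 5.08 and 2.78.

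The immediate early list passed camera at adjusted p = 3.36e-06 (adjusted p = 0.899 with an estimated correlation) with a median log2 fold change of -0.77. Of its 29 members, 8 had an unadjusted p under 0.05 by edgeR, 0 passed over all genes (4 by DESeq2, all lower) and 0 adjusted over the list alone. The mRNA-decay factor Zfp36 stood at 293 ± 115 against 1105 ± 62.0 CPM, Nr4a1 at 192 ± 44.2 against 466 ± 71.6, Ier2 at 173 ± 10.8 against 372 ± 35.1 and Btg2 at 177 ± 50.8 against 454 ± 222 (SD; n = 3 and 2). The list lost its call without sham 2 (adjusted p = 0.0703).

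Tendon and enthesis genes fell by camera (adjusted p = 0.0294; adjusted p = 0.899 with an estimated correlation), and 12 of 30 had a fold above 0. The members with the smallest p were the cartilage intermediate layer proteins Cilp and Cilp2, Egr2, a growth-response transcription factor, and the leucine-rich proteoglycan Prelp. Of these Cilp and Cilp2 passed adjusted over the list alone, and 0 passed over all genes by edgeR (3 by DESeq2: Cilp, Cilp2 and Egr2). Cilp2 stood at 44.3 ± 21.7 against 694 ± 269 CPM and Prelp at 620 ± 182 against 1850.4 ± 1084 (SD; n = 3 and 2), whereas the tendon transcription factor scleraxis (Scx) stood at 67.9 ± 18.6 against 25.2 ± 23.1 CPM (edgeR unadjusted p = 0.0823). The call turned to the opposite direction without sham 2 (adjusted p = 0.705) and was lost without injured 2 (adjusted p = 0.0978).

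Skeletal muscle genes rose (adjusted p = 0.000499; adjusted p = 0.524 with an estimated correlation). The list summed to 270.4 and 61.5 CPM in sham 1 and 2 and to 265, 289 and 148 CPM in injured 1, 2 and 3, so the totals overlapped, whereas the mean levels of 1.01 and 0.69 in sham and from 1.14 to 1.86 log2(CPM + 1) in injured did not. Mb stood at 4.86 ± 5.81 and Ckm at 1.41 ± 0.737 CPM in injured cells (SD, n = 3), with no count in sham control. Of 18 members tested, 16 had a fold above 0 and 0 passed by edgeR over all genes (1 by DESeq2, Mb) or adjusted over the list alone; the median log2 fold change was 2.12, or 1.78 with the 6 members lacking any count in a group set to their bound. Schwann cell genes fell (adjusted p = 0.00149; adjusted p = 0.895 with an estimated correlation), 12 of 14 having a fold below 0 and 0 passing by edgeR over all genes (4 by DESeq2: Mbp, Prx, Mag and Pmp22) or adjusted over the list alone. Myelin basic protein (Mbp) stood at 38.6 ± 44.1 against 870 ± 1073 CPM and Pmp22 at 283 ± 61.9 against 1119 ± 806 (SD; n = 3 and 2). Schwann genes took 0.511% of counts in sham 1, the library richest in blood and endothelial transcripts, and 0.0942% in sham 2. Without sham 1 the Schwann call was lost (adjusted p = 0.0766), and without sham 2 the muscle call (adjusted p = 0.0969).

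The remaining 22 lists did not pass against sham control. Within TGF-beta signalling (camera adjusted p = 0.0752), 24 of 31 genes had a fold below 0. The ligand Tgfb1 stood at 52.3 ± 15.0 against 110 ± 15.0 CPM, the co-receptor Tgfbr3 at 82.9 ± 26.8 against 183 ± 20.7, Ltbp3 at 273 ± 81.0 against 574 ± 41.6 and Smad3 at 47.4 ± 5.31 against 89.2 ± 6.19 (SD; n = 3 and 2). For these 4 genes every injured library was below both sham libraries, with edgeR unadjusted p from 0.0252 to 0.0370. Over the list, 8 members lay wholly below both sham libraries and 2 wholly above. By edgeR 0 members passed over all genes or adjusted over the list alone, and DESeq2 called 0. The log2 fold changes of Tgfb2, Tgfb3, Tgfbr1 and Tgfbr2 were -0.07, -0.24, -0.82 and -0.62. In the cartilage list (adjusted p = 0.0752), Cnmd, Col9a1 and Chad passed adjusted over the list alone and 0 over all genes by edgeR (4 by DESeq2), Cnmd and Col9a1 being higher and chondroadherin (Chad) lower. Col9a1 stood at 454 ± 507 against 8.78 ± 5.23 CPM, with values of 257, 76.0 and 1030.3 in injured 1, 2 and 3, and Chad at 415 ± 186 against 10627 ± 8826 (SD; n = 3 and 2). Sox9, the chondrogenic transcription factor, stood at 216 ± 182 against 623 ± 668 CPM. In the Hedgehog list (adjusted p = 0.0752), 12 of 13 genes had a fold below 0, and Ihh alone passed adjusted over the list alone.

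Among the inflammatory cytokines (adjusted p = 0.700) 15 of 30 genes lay on each side of 0. Cxcl5 and Icam1 passed adjusted over the list alone and 0 over all genes by edgeR (3 by DESeq2), Cxcl5 being higher and Icam1 lower (54.2 ± 21.4 against 317 ± 198 CPM; SD, n = 3 and 2). Wnt (adjusted p = 0.349), BMP (0.199), stem and progenitor (0.199), collagen and crosslinking (0.209), protease (0.936), hypoxia and glycolysis (0.196), oxidative phosphorylation (0.199) and interferon response (0.199) genes had 0 members past either adjustment by edgeR. DESeq2 called 3 (Wnt), 0, 2, 1, 2, 1, 0 and 1 of them in that order. In the bone list (0.535, with 0 past either adjustment by edgeR and 3 by DESeq2) the median log2 fold change was -0.51 and the mean 0.23. The mean was -0.13 with 2 members lacking any count in a group set to their bound. Of DESeq2's bone calls, Phex had counts in injured 3 alone (6.23 CPM) and Sost in injured 2 alone (2.18 CPM). Examples with small unadjusted p were the secreted Wnt antagonist Sfrp4 at 70.3 ± 19.5 against 301 ± 154 CPM, the leptin receptor Lepr at 1.41 ± 1.73 against 58.3 ± 53.3 and Adam12 at 135 ± 22.5 against 34.1 ± 22.3 (SD; n = 3 and 2). Of the other cell types, macrophage (adjusted p = 0.349), neutrophil (0.673), lymphocyte (0.611), endothelial (0.535), smooth muscle and pericyte (0.199), erythroid (0.349), adipocyte (0.604), osteoclast (0.518) and epithelial (0.153) lists did not pass. Stratifin (Sfn) of the epithelial list was the only member of these 9 lists to pass adjusted over the list alone by edgeR. DESeq2 called 1 member each of the lymphocyte, smooth muscle, erythroid, osteoclast and epithelial lists. The lymphocyte gene, Gzma, had counts in injured 1 alone (9.75 CPM) and the erythroid gene, Slc4a1, in sham 1 alone (10.6 CPM). Median and test differed in sign for the endothelial list, with a median of -2.24 and a camera direction upward, and for the lymphocyte list, with a median of -0.67 and the same direction. The means of the lymphocyte (0.48) and osteoclast (0.55) lists opposed their medians (-0.67 each) but were -0.11 and -0.23 with members lacking any count in a group at their bound. For the cytokine list a median of 0.00 stood beside a mean of -0.06.

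Genes coding for surface proteins used in sorting mouse skeletal stem cells were read as a check. Itgav stood at 83.0 ± 43.5 CPM in injured and 51.5 ± 28.9 in sham control, and Cd200 at 64.0 ± 44.1 and 109 ± 42.0 (SD; n = 3 and 2). Of genes usually selected against, the pan-leukocyte gene Ptprc stood at 24.8, 15.1 and 0 CPM in injured 1, 2 and 3 and at 9.95 and 0 CPM in sham 1 and 2. Endothelial Tek stood at 58.1 CPM in sham 1, 0.580 in sham 2 and 61.7 in the uninjured library, against 7.70 ± 2.64 in injured (SD, n = 3). Thy1 reached 14.3 CPM in injured 1 and 11.8 in sham 1, Enpep 16.1 and Eng 201 CPM in sham 1, while sham 2 had no count of Enpep or Eng. None of these genes passed by edgeR or DESeq2, and Runx2, the osteoblast transcription factor, stood at 30.2 ± 27.0 against 20.7 ± 25.4 CPM (SD; n = 3 and 2).

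The second comparison joined the uninjured library to the sham libraries, to set injured cells against all 3 that had no injury. Cell cycle genes rose here too, to 5.06 ± 0.10 from 2.81 ± 0.97 log2(CPM + 1) (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), with 32 of 33 members above 0 (adjusted p = 0.660 with an estimated correlation). Immediate early genes fell, to 7.92 ± 0.24 from 8.80 ± 0.47 (SD, n = 3 each, with exact permutation p = 0.1), with 26 of 29 below 0 (adjusted p = 0.680 with an estimated correlation). The nearest libraries of the 2 sides, injured 3 and sham 1, stood at 8.20 and 8.26. TGF-beta, BMP, Hedgehog, tendon and interferon genes fell and cartilage, collagen, glycolytic and respiratory chain genes rose by camera. None of them passed with an estimated correlation (adjusted p = 0.714 for each), and 0 members passed over all genes by edgeR. Genes with small p that were higher included the pannexin channel Panx3 of cartilage and bone (126 ± 126 against 0.268 ± 0.302 CPM; SD, n = 3 each), and those lower included clusterin (Clu, 140 ± 83.4 against 5619 ± 2545 CPM).

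**Figure D3:**
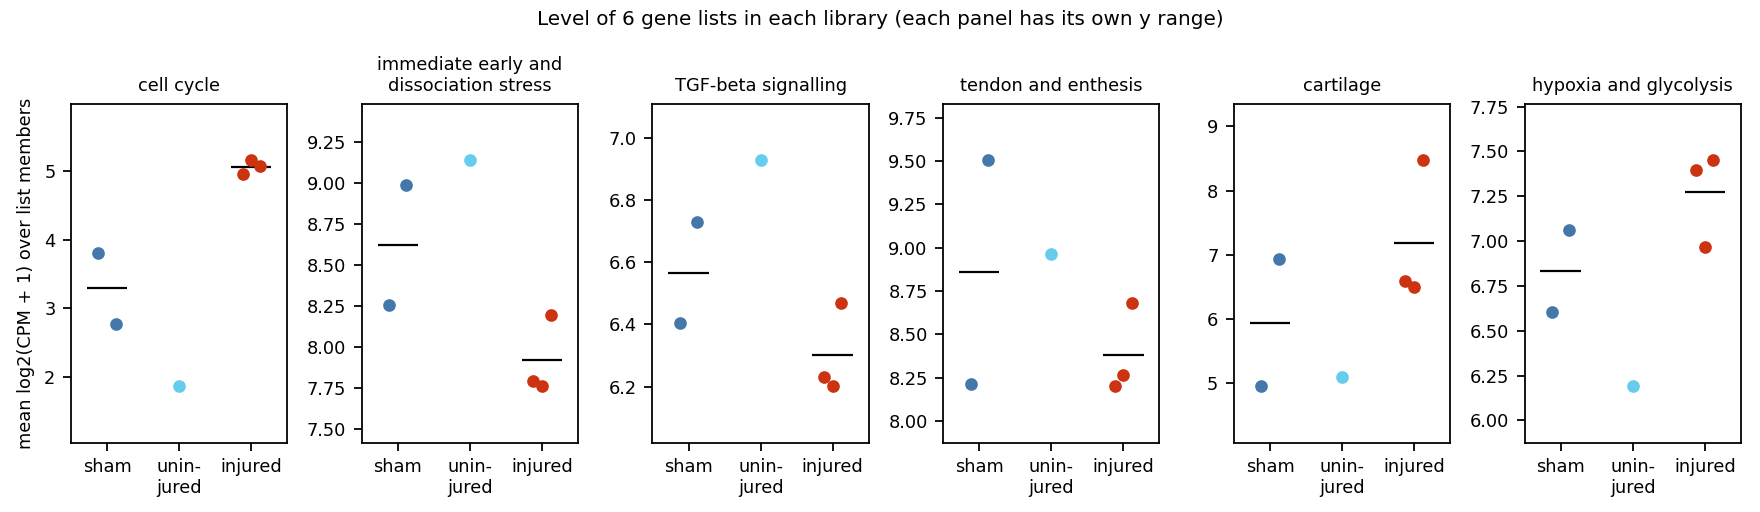
Level of 6 gene lists in each library, as the mean log2(CPM + 1) over list members (y axis, with its own range in each panel), grouped as sham, uninjured and injured on the x axis; lines mark group means. All injured libraries lie above the non-injured ones for the cell cycle list. For the immediate early list they lie below them by a narrow margin (injured 3 at 8.20, sham 1 at 8.26). The groups overlap for the other 4 lists.

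By edgeR no gene of 14110 tested passed (smallest adjusted p = 0.183), and 1049 had an unadjusted p under 0.05, 524 higher and 525 lower. With library size alone as the scaling the split was 648 and 430, and with size factors by relative log expression 468 and 579. DESeq2 called 345 genes (140 higher, 205 lower), limma-voom 7 and edgeR without a low-count filter 5. The 7 genes of limma-voom, all lower, were Chad, Clu, Apod, Gsn, Angptl7, Cilp2 and Cilp, and the 5 without a filter were Ihh and Cnmd (higher) and C7, Apod and Angptl7 (lower). The groups did not overlap for 1303 higher and 998 lower genes, 16.3% of those tested, where chance gives 10%. With sham 1, injured 1 and injured 2 set against the rest, a split not by injury, the share was 20.7%. Further genes with small p were the replication genes Timeless (11.2 ± 5.28 CPM in injured, 1 count in all non-injured libraries) and Dtl (18.1 ± 12.6 against 0.126 ± 0.123 CPM), the pyrophosphatase Ppa1 (log2 fold change 2.28 ± 0.40, SE) and the mitotic kinase Nek6 (1.89 ± 0.34). Lower were Hs3st1 (-4.37 ± 0.60), Fam124a (-3.28 ± 0.45), Cilp2 (-4.27 ± 0.59), Clu (-5.33 ± 0.75) and the proteoglycan Gpc3 (-3.46 ± 0.50). Kif23 and Ihh had no count in any of the 3 non-injured libraries and were at least 1087-fold and 2246-fold above them.

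Of the 27 lists, 14 passed camera and 0 with an estimated correlation. The cell cycle list had an adjusted p of 9.13e-13 (adjusted p = 0.660 with an estimated correlation), 0 members past over all genes by edgeR (5 by DESeq2) and 1 adjusted over the list alone (Kif23). The immediate early list had an adjusted p of 1.35e-08 (adjusted p = 0.680 with an estimated correlation), 0 members past over all genes by edgeR (9 by DESeq2) and 8 adjusted over the list alone: Fosb, Junb, Jund, Ier2, Zfp36, Btg2, Nr4a1 and Socs3, all lower. Both lists held with any 1 library left out.

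The TGF-beta list fell (adjusted p = 0.0147), 24 of 31 genes having a fold below 0, with 0 past by edgeR over all genes or adjusted over the list alone. DESeq2 called 3 TGF-beta, 1 BMP, 7 tendon, 3 cartilage, 5 collagen, 1 glycolytic, 0 respiratory and 1 interferon genes, and limma-voom 2 tendon and 1 cartilage genes. The TGF-beta list's p was 0.714 with an estimated correlation, as it was for the BMP, Hedgehog, tendon, cartilage, collagen, interferon, hypoxia and glycolysis, oxidative phosphorylation and Schwann lists (adjusted p = 0.714 with an estimated correlation for each). The BMP list fell at adjusted p = 0.0176 with 22 of 29 below 0, and the Hedgehog list at 0.0147 with 11 of 12 below 0, Ihh being the exception. The tendon list fell at 0.0147, with 19 of 30 below 0, and Cilp, Cilp2 and Egr2 passed adjusted over the list alone. Without the uninjured library the TGF-beta (adjusted p = 0.0772), Hedgehog (0.0772) and BMP (0.204) calls were lost, and without sham 2 the TGF-beta (0.0557), Hedgehog (0.0557) and tendon (0.469) calls; the BMP call was also lost without injured 1 (0.154).

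The cartilage list rose at adjusted p = 0.0158, with 18 of 23 above 0 and Cnmd, Col9a1 and Chad past adjusted over the list alone, of which Chad was lower. Collagen and crosslinking genes rose at 0.0387, with 21 of 31 above 0, among them the lysyl oxidase Loxl2 (663 ± 155 CPM in injured, SD, n = 3; log2 fold change 1.23 ± 0.35, SE) and the lysyl hydroxylase Plod3 (1.86 ± 0.53). Hypoxia and glycolysis genes rose at 0.0255, with 20 of 25 above 0, including Pgk1 (1.43 ± 0.53), Pgam1 (1.27 ± 0.44) and Ldha (1.26 ± 0.53). The 1 gene of that list past adjusted over the list alone was Ndrg1, which was lower (-2.11 ± 0.41). Oxidative phosphorylation genes rose at 0.0147, with 28 of 30 above 0, and interferon response genes fell at 0.0372, with 20 of 24 below 0; the collagen, respiratory and interferon lists had 0 members past either adjustment by edgeR. These 5 calls were lost without sham 1 and injured 1, the libraries richest in blood transcripts, at adjusted p = 0.334 (cartilage), 0.526 (collagens), 0.157 (glycolysis), 0.112 (respiration) and 0.444 (interferon). Leaving out single libraries ended them as well: the uninjured library all 5 (adjusted p = 0.0589, 0.204, 0.176, 0.204 and 0.176 in that order), sham 1 the cartilage (0.155), collagen (0.214), glycolysis (0.0659) and interferon (0.692) calls, and injured 3 the same 4 (0.126, 0.126, 0.0833 and 0.361). Injured 1 ended the collagen (0.263), glycolysis (0.154) and respiration (0.430) calls, and sham 2 the respiration call (0.0557).

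Skeletal muscle genes rose (adjusted p = 0.00337; adjusted p = 0.660 with an estimated correlation), and Schwann (adjusted p = 0.0253; adjusted p = 0.714 with an estimated correlation) and epithelial genes fell (adjusted p = 0.0208; adjusted p = 0.660 with an estimated correlation), with 0 members past either adjustment by edgeR and, by DESeq2, Pmp22 alone. Epithelial genes summed to at most 111 CPM in any library. The uninjured library had levels of 2.39 (Schwann) and 0.69 (epithelial) log2(CPM + 1), against injured means of 2.73 and 0.56 and sham means of 4.46 and 1.34. The Schwann call was lost without sham 1 (adjusted p = 0.403), sham 2 (0.103), injured 2 (0.146) or injured 3 (0.0678), the epithelial call without sham 1 (0.158), sham 2 (0.0610) or injured 3 (0.0650), and the muscle call without sham 2 (0.0557). The Schwann (0.187) and epithelial (0.0875) calls were also lost without sham 1 and injured 1. Of the 13 lists that did not pass, Wnt (adjusted p = 0.181) had 3 genes past adjusted over the list alone, Fzd4 and Sfrp4 lower and Sfrp1 higher, and inflammatory cytokines (0.479) had 2, Cxcl5 higher and Tnfaip3 lower. The others were bone (0.109), stem and progenitor (0.181), protease (0.951), macrophage (0.0622), neutrophil (0.848), lymphocyte (0.128), endothelial (0.820), smooth muscle (0.181), erythroid (0.951), adipocyte (0.951) and osteoclast (0.479), none with a member past either adjustment by edgeR. DESeq2 called 4 bone, 2 stem and progenitor, 2 protease and 1 smooth muscle genes. Camera's upward direction stood against a negative median for the erythroid (-2.54), lymphocyte (-0.40) and adipocyte (-0.03) lists, and against a mean of -0.12 for the proteases. Beside the cell cycle and immediate early lists, the mean levels of 3 lists did not overlap between the groups (exact permutation p = 0.1 for each). Chance gives such a separation in 10% of the 27 lists. Muscle was 0.58 log2 units higher in injured, and epithelial stood at 0.56 ± 0.12 against 1.12 ± 0.42 log2(CPM + 1) (SD, n = 3 each). Stem and progenitor stood at 5.77 ± 0.27 against 6.10 ± 0.03 (SD, n = 3 each) and did not pass camera. Its summed level went the other way, at 6125 ± 1023 CPM in injured against 4850 ± 1303 (SD, n = 3 each).

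The uninjured library, of which there is 1, was set beside sham control without a test. For the 10 genes named from injured against sham control, it lay on the sham side of all injured libraries in 10. Gtse1 stood at 6.65 CPM in it, and DESeq2's log2 fold change for Gtse1 against all non-injured libraries was 2.54 (adjusted p = 0.832). Several of its values went beyond the sham libraries: Angptl7 stood at 4207 CPM against 1336 and 775 in sham 1 and 2, and Sfrp4 at 910 against 192 and 410. Its cell cycle level of 1.86 was below those of sham 1 (3.81) and sham 2 (2.78), and its immediate early level of 9.14 above theirs (8.26 and 8.99). Of 819 genes with an unadjusted p under 0.05 when injured was set against sham control without it, it lay closer to the sham than the injured mean in 616 (75.2%). For each sham library the genes were chosen against the other sham library alone, and closeness was measured to that library alone. The shares were 34.0% for sham 1 and 21.5% for sham 2. Genes chosen on 1 library carry its own noise, so these shares cannot be set against the 75.2%. The measure was chosen after the data were seen.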

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

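Leaving out sham 1 and injured 1 together, and removing ribosomal RNA genes and Lars2, were chosen after the data were seen. Where a left-out library leaves 1 sham library, that library is assumed to vary like the other groups. No gene passed edgeR's threshold with other scalings, the stricter filter, a threshold of 0.1, a block, or any library left out, in either comparison. Against sham control at a threshold of 0.1, edgeR called 32 genes without sham 1 and injured 1 (smallest adjusted p = 0.0675) and 2 with ribosomal RNA genes and Lars2 removed (0.0889). Counts of genes moved with the tool: against sham control DESeq2 called 369, limma-voom 1 and edgeR without a low-count filter 3, and against all non-injured libraries 345, 7 and 5.

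Of the 5 lists called against sham control, 0 were called with an estimated inter-gene correlation and 0 by fry's directional test. Of the 14 called against all non-injured libraries the counts were likewise 0 and 0. Fry's mixed test asks for change in either direction, not a shared one. Against sham control it passed Hedgehog (adjusted p = 0.00476), cell cycle (0.0149), tendon (0.0168) and muscle (0.0443). Immediate early (0.0850) and Schwann (0.286) genes did not pass it. Several lists passed it against all non-injured libraries. Without the sham and injured libraries richest in blood transcripts 9 lists were called in each comparison. With single libraries left out the count ran from 5 to 14 against sham control, reaching 14 without sham 1, 11 without sham 2 and 11 without injured 3. Against all non-injured libraries it ran from 6 to 13, falling to 6 without the uninjured library and 9 without sham 2. The cell cycle call held with every single library left out in both comparisons, at adjusted p of at most 0.000135 and 1.69e-09.

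Replicate numbers shared by sham and injured titles were not taken to pair the samples, since no label says that a number marks a common animal or day. The deviations of the 2 pairs that share a number correlated at 0.353 and 0.0107, and those of sham 2 and injured 3 at 0.434. With 2 sham libraries their deviations mirror each other, so these values cannot decide on pairing. With a replicate block 0 genes passed, and 12 lists were called in 4 libraries against sham control (10 with no block in the same 4) and 12 against all non-injured libraries. Under the block the neutrophil list turned upward at adjusted p = 0.0392 against sham control and 0.0339 against all non-injured libraries. The block ended the calls of the cartilage (0.368), collagen (0.379), interferon (0.640) and glycolysis (0.190) lists against all non-injured libraries and no other list call.

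Directions that turned against sham control with a library left out were those of the tendon list without sham 2 (adjusted p = 0.705; range 9.40e-06 to 0.705), the macrophage list without sham 2 (0.0409; 5.66e-05 to 0.715) and the endothelial list without sham 2 (3.59e-07; 1.34e-13 to 0.915). The neutrophil (0.0299; 0.0190 to 0.715) and erythroid lists (0.0283; 0.000311 to 0.949) turned without sham 1. Log2 fold changes of Timp4 ranged from -4.06 to 0.85 and of Mag from -7.71 to 0.57, the positive values without sham 1; without sham 1 and injured 1 they were 1.00 and 0.19. The cause was not tested. Over all alternatives, the 27 lists kept their side of the threshold in 713 cases, lost a call in 89, gained one in 55 and turned in 7. The named genes kept side in 3985, gained a call in 123 and turned in 4. Changes of sign were more frequent, 70 for lists and 96 for named genes, the others being of values not called. With the dispersion of these libraries (0.959 to 1.21), a change of 2 log2 units was rarely recovered in simulations by edgeR over all genes.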

Other observations

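Apart from Ihh and Panx3, the genes in the next paragraph were chosen after their values were seen. The tests that leave out the libraries richest in blood transcripts, the overlap of DESeq2's calls, and the splits for edgeR's counts and for the lists were also chosen only after the result was seen.

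Cartilage genes did not all move the same way, although 18 of 23 members of the cartilage list had a fold above 0 against all non-injured libraries and 5 below. Ihh and Panx3, genes of maturing growth cartilage, were higher in every injured library, whereas Col10a1, the collagen of hypertrophic cartilage, stood at 27.4, 23.7 and 77.8 CPM in the injured libraries and at 5.22, 101 and 21.4 CPM in sham 1, sham 2 and the uninjured library. Cytokine-like 1 (Cytl1), a secreted cartilage protein, stood at 0, 29.8 and 30.2 CPM in injured against 722, 1301 and 1382 CPM. The Hedgehog target Gli1 stood at 0, 0.0330 and 4.88 CPM against 9.79, 7.43 and 32.6 CPM, whereas Ihh, a ligand of that pathway, had counts in the injured libraries alone. The actin-severing protein gelsolin (Gsn) was at 1324, 895 and 1002 CPM in injured, and at 10562, 8243 and 25135 CPM in the non-injured libraries. Tenascin C (Tnc) was at 940, 478 and 925 CPM in injured against 134, 393 and 136 CPM. Xist was at 7.88 CPM in injured 1 and had no count elsewhere, while the Y-linked gene Ddx3y lay between 25.7 and 83.5 CPM in all 6 libraries.

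Cell cycle genes were 2.25 log2 units higher in injured than in non-injured libraries. Lower detection in the non-injured libraries is argued against by random lists matched on expression, of which 0% of 10000 rose as much (highest 0.62). Without sham 1 and injured 1 the difference was 2.80, or 124% of that in all 6, so it did not rest on these 2 libraries. Sham 1 had the highest non-injured level (3.81) and injured 1 the lowest injured one (4.96), so leaving both out could only widen it. Injured 2 also held more macrophage transcripts (0.229%) than sham 2 (0.00491%) and the uninjured library (0.0272%). Blood and marrow cells are therefore not excluded, although injured 3, at 0.00619% macrophage transcripts, had a level of 5.08. Whether more of the sorted cells were cycling after injury or the mixture within the sort gate differed stays open, as no value here separates them. Of 10 splits of the 6 libraries, the real one included, 3 called at least as many lists as the real one (14, highest other 18). These 10 splits are too few for a share under 0.05. Camera's unadjusted p for the cell cycle list was 3.38e-14 in the real split and as low as 8.30e-09 in another, and it was under 0.05 in 5 of the other 9.

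Immediate early genes were 0.88 log2 units lower in injured. Of 10000 random lists matched on expression, 0% fell as much (lowest -0.73), so the list fell relative to genes of like level. The random lists were drawn after TMM scaling, which levels the bulk of genes between libraries. Their genes were also drawn independently, whereas the estimated correlation of the list was 0.343. This comparison therefore cannot decide whether scaling of the libraries contributed. The separation of the groups was narrow, with injured 3 at 8.20 and sham 1 at 8.26 log2(CPM + 1). As summed shares of counts without TMM scaling the groups overlapped (injured 2 at 1.69%, sham 1 at 1.61%). Without sham 1 and injured 1 the difference was -1.09, or 124% of that in all 6. Sham 1 had the lowest non-injured level, so leaving it out could only widen the difference, and blood and marrow cells are not excluded. Immediate early genes respond to tissue digestion, so a difference in handling time between groups may account for the fall as well as injury could. No label records handling time.

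DESeq2 called 345 genes against all non-injured libraries and edgeR 0. Genes high in 1 library only are argued against as the reason for most calls against sham control, where the low-count filter asks for counts in 1 library: without DESeq2's outlier and count filters, 25.5% of 369 genes had overlapping groups or over 90% of their summed CPM in 1 library, so they account for part of the count. Against all non-injured libraries the share was 3.18% of 346 genes, but there the low-count filter asks for counts in 3 libraries and can remove such genes beforehand, so that share leaves the explanation open. Of the 10 splits, the real one included, 2 gave at least as many DESeq2 calls as the real one (highest other 503). By the same counting, 2 gave at least as many genes at an edgeR unadjusted p under 0.05 (real 1049, highest other 1401). These 10 splits are too few for a share under 0.05. EdgeR's count of 0 cannot be weighed this way, since all 10 splits give as many whatever the data. The split that exceeded the real one set sham 1, injured 1 and injured 2, with the largest shares of erythroid and macrophage transcripts, against the rest, and it points to a structure of the samples other than injury. Without sham 1 and injured 1, edgeR called 0 genes in either comparison and camera 9 lists in each.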
